A study of Mus musculus with 30 samples.

How the data were processed

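Bulk RNA was sequenced from the colon of male C57BL/6 mice, wild-type (WT) or carrying a deletion of Smox (spermine oxidase, written Smox in the sample labels), at day 56 of the experiment. The 30 libraries fall into 10 groups of 3 by genotype, treatment and tissue as the labels give them. According to the labels RNA was purified with RNeasy columns and libraries were made with the NEBNext Ultra II Directional kit. The submitters' notes name fastp, Salmon and DESeq2 and the mouse build GRCm38, without versions or settings. The deposited table holds expected_counts (estimated counts per gene, whole numbers as the authors deposited them) for 31023 genes in 30 libraries, with a symbol for 20430 of the genes. Of the 10593 genes without a symbol, 10546 were named from GENCODE vM21 by their identifier, which also gave coordinates on GRCm38, and 30965 genes of the table were found in it. A group of 45 symbols is used by more than 1 gene, so genes were joined by identifier. No gene in the table had fewer than 2 counts in total.

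Library totals ran from 33060607 to 81011304 counts. The labels give no sequencing batch, date or cage, and nothing in them pairs samples or says whether a tumor and a non-tumor sample came from the same mouse. A WT group with tumors after AOM-DSS alone and a Smox group with tumors after AOM-DSS with spermidine were not analysed here. Spread between replicates covers counting error and differences between mice, and counts of a library are not independent molecules.

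Genes were tested with edgeR 4.0.16 in R 4.3.3. Libraries were scaled by TMM, and filterByExpr with a minimum count of 10 and a minimum total of 15 kept 19558 genes and removed 11465, which held a median of 0.0165% of a library's counts. A single quasi-likelihood model with 1 mean per group and robust settings was fitted to the 30 libraries, with 20 residual degrees of freedom. The common dispersion was 0.177 and the median prior degrees of freedom 2.73. In each of 17 contrasts p values were adjusted by Benjamini-Hochberg over all genes tested, at 0.05. Expression per group is given as CPM, the count of a gene scaled to the size of its library, mean with standard deviation, n = 3 in every group. Fold changes are those of the model and their standard errors (SE) are on the log2 scale. A gene "rose" or "fell" where its adjusted p was under 0.05.

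Lists of genes for pathways and cell types were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2, a preset inter-gene correlation of 0.01, and adjustment over the lists of a comparison. The 33 lists cover polyamine metabolism, neutrophil and acute inflammation, interferon response, epithelial antimicrobial response, Wnt target genes, cell cycle, regenerative epithelium and YAP targets, NRF2 and redox enzymes, p53 targets, cholesterol synthesis, xenobiotic metabolism, extracellular matrix and remodelling, colonocyte, goblet cell, enteroendocrine cell, tuft cell, Paneth cell, alpha-defensins, smooth muscle, B and plasma cell, T and NK cell, macrophage, enteric neuron and glia, endothelium, adipocyte, pancreas, small intestine enterocyte, squamous epithelium, red cell, distal hindgut position genes, clock genes, immediate early genes and the mitochondrial genome. A list of skeletal muscle genes was added after seeing the data and has no camera test. Each camera call was repeated with a correlation estimated from the data and with fry, which tests whether the genes of a list move one way on balance.

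Genes to be named were chosen by rule. In each comparison they were Smox, up to 8 called genes with the largest rise and up to 8 with the largest fall among those with a mean of at least 2 CPM in the higher group, at least 3 counts in the lower group and no overlap between groups, and up to 4 called members per list. A list with no called member could be illustrated by its 2 highest expressed members, and an interaction by up to 5 genes per direction. Predicted genes, immunoglobulin and T cell receptor segments, mitochondrial genes, genes of the Y chromosome, Xist and pseudogenes were left out of the rule on rises and falls. Genes without any count in a whole group are not given a fold change.

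The groups, the comparisons and their tests, the 33 lists, the rule for named genes and the first set of alternatives were chosen before the data were examined. Those alternatives were DESeq2 1.42.0, RLE scaling, no filter, a filter of 1 CPM in 3 libraries, a model of only the groups compared, an estimated inter-gene correlation, fry, other windows around Smox and leaving out each library in turn. A model with the mean level of the distal hindgut position genes as a covariate and a model without a pair of atypical libraries were chosen after seeing the data. The procedure was tested on simulated data by changing 200 genes between groups in 4 of the comparisons, where 46, 58, 57 and 46% of 2-fold changes and 89, 86, 87 and 83% of 4-fold changes were recovered and 4.93, 7.69, 1.37 and 4.44% of calls were false. Sequence copies of Eif3j1, Eif3j2, Pcna-ps2 and Gm18234 were sought with blastn 2.17.0 among the annotated transcripts of GENCODE vM21, so copies outside the annotation could not be found. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.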

Results

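RNA of the mouse colon was sequenced in a model of colitis-associated cancer to ask how loss of spermine oxidase and a supply of spermidine change the tissue. Spermine oxidase, encoded by Smox, turns spermine into spermidine and releases hydrogen peroxide. Male C57BL/6 mice aged 8 to 12 weeks were WT or carried the Smox deletion. Some drank 14 mM spermidine in their water for 56 days. Others received a dose of 12.5 mg/kg azoxymethane, a colon carcinogen, and then 3 cycles of 4% dextran sulfate sodium, which injures the colon lining, for 5 days each from days 5, 26 and 47 (AOM-DSS), with or without spermidine. The 10 groups of 3 libraries were untreated colon, colon after spermidine, non-tumor colon after AOM-DSS and non-tumor colon after AOM-DSS with spermidine, each in WT and Smox mice, and tumors of WT mice after AOM-DSS with spermidine and of Smox mice after AOM-DSS alone.

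Library totals, in counts, were 67255670 to 72268614 in untreated WT, 53101147 to 81011304 in untreated Smox, 58486221 to 64240604 in WT with spermidine and 58839099 to 68632794 in Smox with spermidine. After AOM-DSS they were 52484764 to 60127900 in WT and 50706102 to 56547616 in Smox non-tumor colon, and with spermidine added 33060607 to 64655937 in WT and 51779747 to 68035606 in Smox. Tumors had 52769642 to 56534966 in WT and 54801962 to 58822886 in Smox. The first principal component of the 1000 most variable genes held 47.4% of their variance and placed the 6 tumors between 43.0 and 111, against -70.9 to 18.4 for the other libraries except Smox AOM-DSS spermidine non-tumor replicate 1 at 61.8.

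Several libraries stood apart from their groups, of which WT untreated replicate 3 and Smox AOM-DSS spermidine non-tumor replicate 1 are the pair called atypical. In WT untreated replicate 3 the mitochondrial genome held 21.7% of counts, against 2.57 to 9.91% in the other libraries. Its skeletal muscle genes had a mean log2 CPM of 9.39, and its distal hindgut position genes, Hox genes and others that mark the distal end of the gut, had 0.19 where the group mean was 3.87 ± 3.19. Smox AOM-DSS spermidine non-tumor replicate 1 had a mean log2 CPM of 6.19 for Wnt target genes, close to the 6.19 ± 1.24 of Smox tumors, where the lowest of its group had 2.54. Smox tumor replicate 3, which was kept, lay at 43.0 on the first component where the other Smox tumors lay at 101 and 107. Skeletal muscle genes had 6.75 in Smox spermidine replicate 1. Squamous epithelium genes, such as Krt13 of the lining near the anus, had 6.83 in Smox untreated replicate 3, 4.82 in Smox spermidine replicate 2 and 3.70 in WT spermidine replicate 1. The position genes were at 3.46 ± 2.10 in WT and 1.94 ± 0.55 in Smox non-tumor colon after AOM-DSS, and at 5.91 ± 0.18 in WT and 1.97 ± 1.31 in Smox when spermidine was added.

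**Figure D1:**
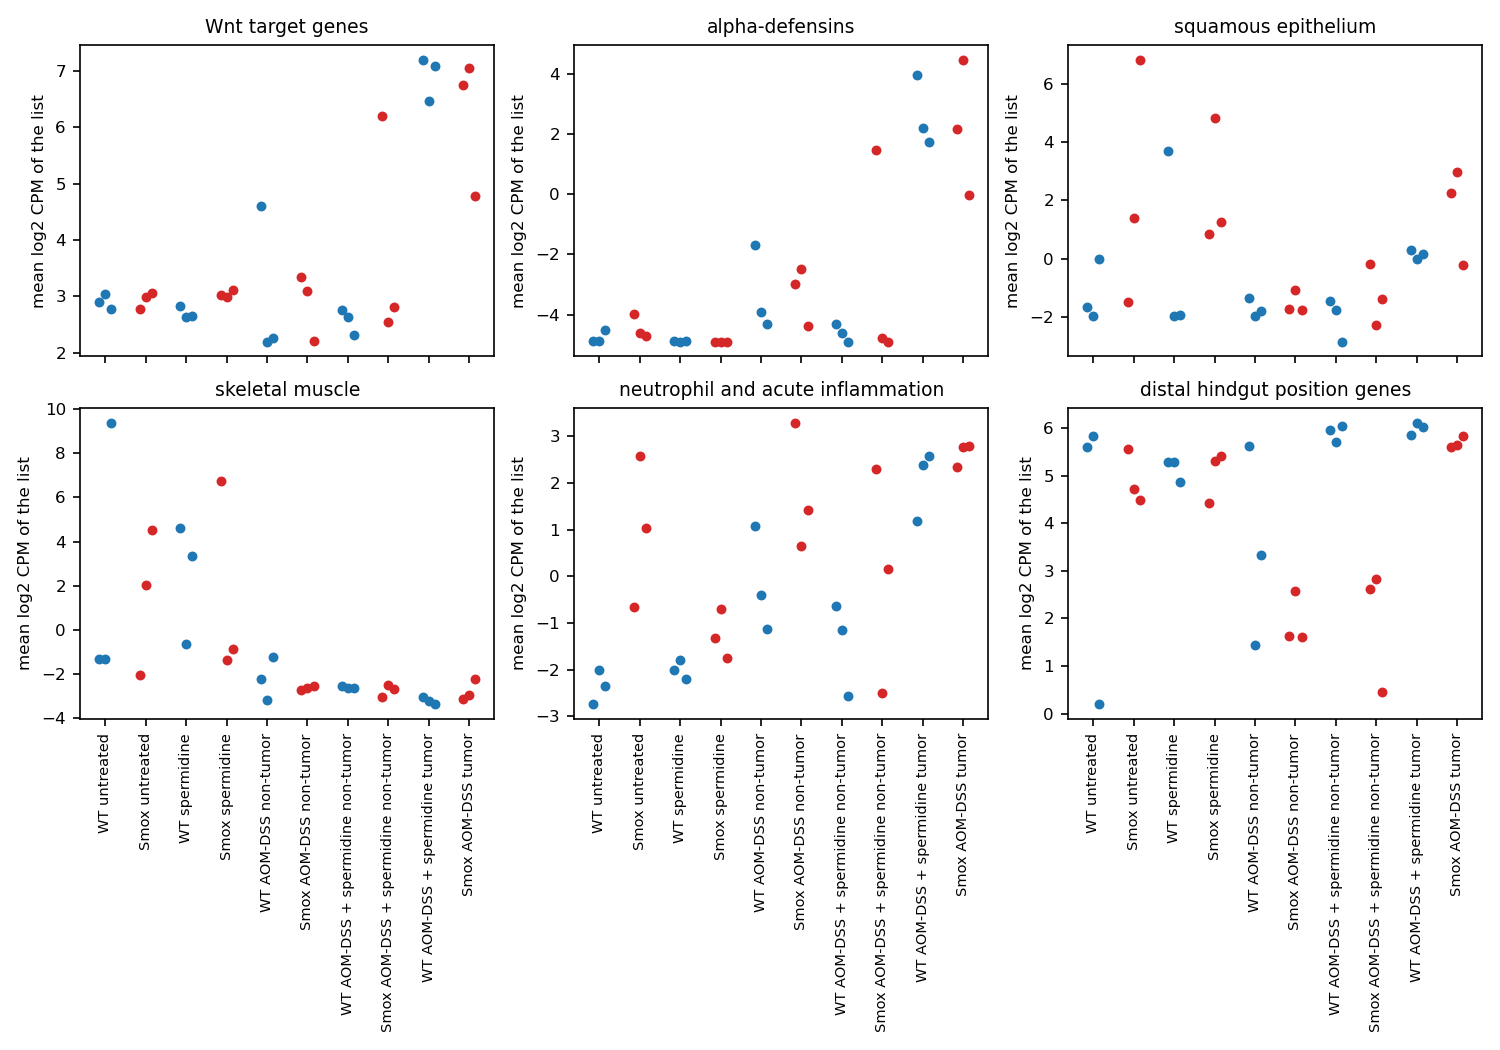
Mean log2 CPM of 6 gene lists in each library, by group (blue WT, red Smox). Wnt target genes and alpha-defensins are highest in the tumor groups, and skeletal muscle genes reach 9.39 in 1 untreated WT library.

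The genotype labels were compared with the RNA first. Smox itself (ENSMUSG00000027333.18, GRCm38 chromosome 2, 131491496 to 131525922) was transcribed in the libraries labelled Smox, at 18.6 to 68.7 CPM against 25.1 to 169 CPM in WT libraries. In untreated colon its level was 30.8 ± 4.78 CPM in Smox and 26.5 ± 1.23 CPM in WT (1.16-fold, adjusted p = 0.62). With spermidine it was 22.7 ± 4.02 CPM in Smox and 47.3 ± 3.15 in WT (2.09-fold, adjusted p = 0.153), after AOM-DSS 29.9 ± 5.25 and 46.9 ± 4.61 (1.57-fold, adjusted p = 0.496), and with both 40.5 ± 20.5 and 49.4 ± 4.05 (1.22-fold, adjusted p = 0.628). It was lower in the libraries labelled Smox among tumors, where the WT mice alone had drunk spermidine, 56.8 ± 12.4 against 140 ± 25.3 CPM (2.46-fold, adjusted p = 0.0357). The labels do not say which part of the gene was removed.

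Another gene of chromosome 2 parted the genotypes. Eif3j1 (ENSMUSG00000027236.8, 122028546 to 122056598), a subunit of a translation initiation factor, had 38.9 ± 5.96 CPM in WT and 3.36 ± 0.81 CPM in Smox libraries (n = 15 each), with no overlap. Its copy Eif3j2 (chromosome 18, 43475418 to 43477796) was higher in Smox, 70.9 ± 10.96 against 39.4 ± 7.23 CPM, and the sum of both was 74.3 ± 11.5 in Smox and 78.3 ± 12.7 in WT. Jmjd7 (120027483 to 120032594), a protein lysyl hydroxylase, had 0.76 CPM in Smox and 7.85 in WT, and Spg11 (122053520 to 122118386), which serves lysosome function, 17.4 and 41.1. Adal (121140428 to 121156680), an adenosine deaminase-like enzyme, had 13.8 CPM in Smox and 6.27 in WT, and Bloc1s6 (122738503 to 122749475), a part of a complex that forms lysosome-related organelles, 49.2 and 33.1. The processed pseudogenes Pcna-ps2 (chromosome 19, 9283380 to 9284160) and Gm18234 (chromosome 16, 27843362 to 27844412) also differed, Pcna-ps2 with 12.1 CPM in Smox and 0.05 in WT. Of these 8 genes 5 (Eif3j1, Jmjd7, Spg11, Pcna-ps2 and Gm18234) passed the test in each of 5 comparisons of Smox with WT, and 5 of the 8 lie on chromosome 2, which holds 7.44% of 19541 tested genes with a position. Genes within 5 Mb of Smox were not called more often than others by Fisher's exact test (9 of 116 in untreated colon, adjusted p = 0.569). Within 10 Mb they were, with 20 of 166 called in untreated colon (adjusted p = 0.00253), 3 with spermidine (0.000622), 4 after AOM-DSS (1.35e-05) and 4 after AOM-DSS with spermidine (0.00105).

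**Figure D2:**
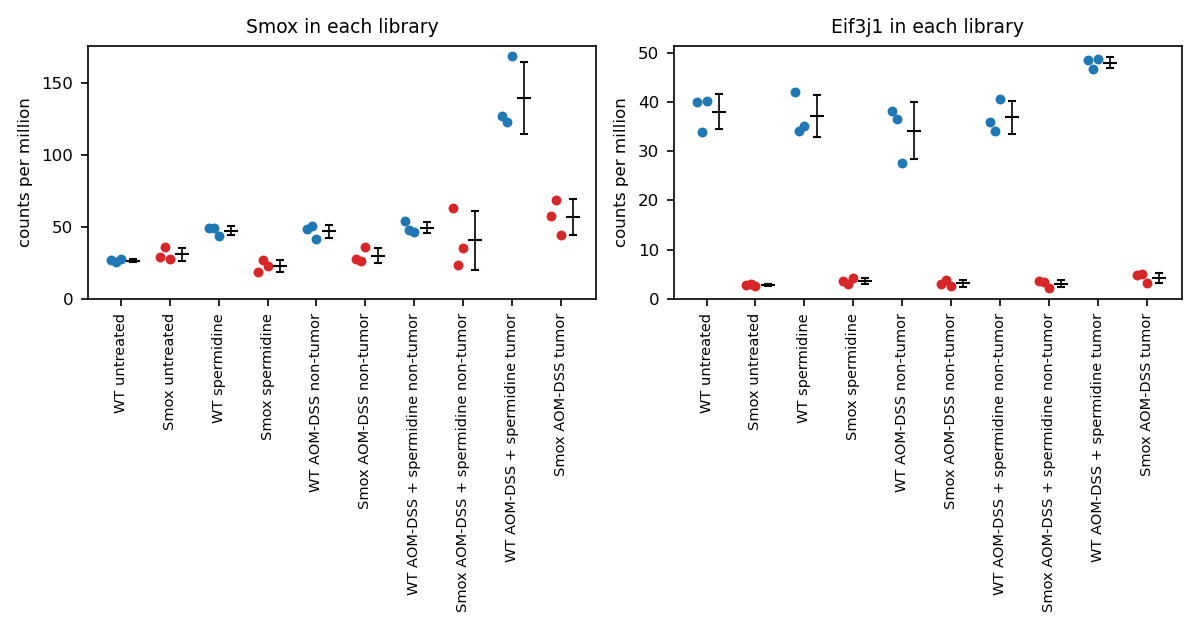
CPM of Smox and Eif3j1 in each of 30 libraries (points) with group mean and standard deviation, n = 3 per group (blue WT, red Smox). Eif3j1 lies between 2.20 and 4.93 in Smox libraries and between 27.6 and 48.9 in WT libraries, while Smox overlaps between genotypes.

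In untreated colon, which asks what loss of Smox does by itself, genes of inflammation and barrier defence were higher in Smox and genes of neurons and mitochondria lower. Nos2, the inducible nitric oxide synthase, was at 110 ± 71.8 CPM in Smox and 5.77 ± 5.23 in WT (18.9-fold, log2 SE 1.06, adjusted p = 0.0271). Reg3g, an antibacterial lectin of the epithelium, was 57.7-fold higher (36.8 to 460 CPM against 3.49 ± 3.19, adjusted p = 0.0363), and lactoferrin, Ltf, 286-fold higher (150 ± 215 CPM, adjusted p = 0.0215). S100a9, a calcium-binding protein of neutrophils, rose 274-fold to 23.6 ± 19.7 CPM. The goblet cell genes Spdef (4.82-fold, adjusted p = 0.0385) and Spink4 (2.86-fold, adjusted p = 0.0277) rose as well. Neuronal Elavl4 fell 9.47-fold (adjusted p = 0.0242) and Tubb3, a neuronal tubulin, 7.28-fold (adjusted p = 0.0215).

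As lists, neutrophil and acute inflammation genes were higher in 28 of 28 members, 12 of which rose, or 22 adjusted over the list alone (camera adjusted p = 1.91e-12, adjusted p = 0.443 with an estimated correlation). Of 17 epithelial antimicrobial genes 6 rose, or 11 adjusted over the list alone (4.62e-07, adjusted p = 0.0284 with an estimated correlation). Macrophage genes (3 of 15 rose, 9 adjusted over the list alone, 5.79e-06, then adjusted p = 0.521 with an estimated correlation) included the complement gene C1qa, 3.09-fold higher. B and plasma cell genes (3 of 16 rose, 5 adjusted over the list alone, 2.22e-06, then adjusted p = 0.569 with an estimated correlation) included Igha, the heavy chain of IgA, 11.2-fold higher. The T and NK cell list was higher with none of 18 called and 2 adjusted over the list alone (1.84e-06, adjusted p = 0.569 with an estimated correlation). Of enteric neuron and glia genes 8 of 15 fell, or 15 adjusted over the list alone (1.50e-11, adjusted p = 0.370 with an estimated correlation), and of the mitochondrial genome 15 of 15 (1.79e-14, adjusted p = 0.370 with an estimated correlation), mt-Atp6 from 10700 ± 8240 to 1777 ± 199 CPM. Smooth muscle genes were lower with none of 15 called (6.81e-05, adjusted p = 0.643 with an estimated correlation), Myh11 with 515 ± 350 against 1734 ± 525 CPM, and skeletal muscle genes were highest in WT untreated replicate 3. The squamous list, of which 5 of 14 members rose, moved the same way (10 adjusted over the list alone, 0.00100, adjusted p = 0.643 with an estimated correlation), with Krt13 at 165 ± 263 CPM in Smox, and was no longer called without Smox untreated replicate 3 (0.362). In all, 515 genes rose and 649 fell. This count rests on few libraries, since it was 17 without WT untreated replicate 3, 6 without Smox untreated replicate 2 and 6 without Smox untreated replicate 3. With both atypical libraries left out it was 32, of which 29 were shared. Of the genes chosen by rule to be named for this comparison and lying outside chromosome 2, mt-Atp6 (0.0353) and Il17a (193-fold higher, 0.0481) stayed past the threshold.

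**Figure D3:**
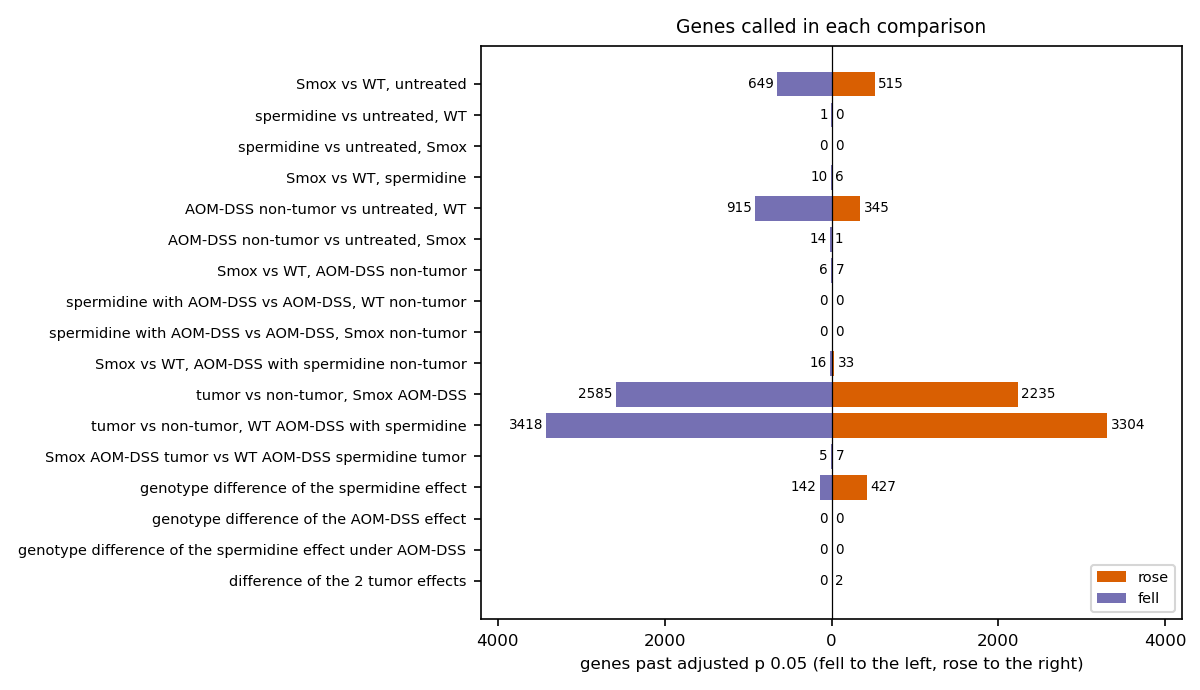
Numbers of genes that fell (left) and rose (right) at an adjusted p of 0.05 in each of 17 comparisons, edgeR, 19558 genes tested. The 2 tumor comparisons hold the most genes, 4820 and 6722.

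Spermidine alone, given to ask what the supplement does in healthy colon, moved few single genes. In WT mice 1 gene was called, Tmx4 (chromosome 2, 134594185 to 134644145), a thioredoxin-related membrane protein of the endoplasmic reticulum, which fell 2.39-fold from 27.4 ± 0.90 to 11.4 ± 1.13 CPM (log2 SE 0.19, adjusted p = 0.0151). Smox was at 47.3 ± 3.15 CPM with spermidine and 26.5 ± 1.23 without (1.79-fold, adjusted p = 0.124). Enteric neuron and glia genes were lower as a list, with 0 of 15 called and 13 adjusted over the list alone (camera adjusted p = 3.23e-09, adjusted p = 0.832 with an estimated correlation); of them Ret, the receptor of enteric nerve growth, had 7.77 ± 2.28 CPM against 35.6 ± 26.5. The mitochondrial genome was lower (2.83e-05, adjusted p = 0.928 with an estimated correlation), and colonocyte and goblet cell genes were higher (0.00436 and 0.00432, adjusted p = 0.928 with an estimated correlation for both), Muc2, the main mucin, with 2498 ± 2390 against 627 ± 99.5 CPM. The mitochondrial call ended without WT untreated replicate 3 (0.432), the colonocyte call without WT untreated replicate 2 (0.100) or WT spermidine replicate 3 (0.0777), and the goblet cell call without WT untreated replicate 3 (0.191) or WT spermidine replicate 1 (0.0971). In edgeR 3152 genes had an unadjusted p under 0.05, and DESeq2 called 910. Without WT untreated replicate 3 the count was 7, without either of the other 2 untreated libraries, WT spermidine replicate 1 or replicate 3 it was 0, and without both atypical libraries 52.

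In Smox mice no gene passed the test for spermidine in edgeR, with 1825 at an unadjusted p under 0.05, and DESeq2 called 46. As lists, epithelial antimicrobial genes were lower with spermidine (0 of 17 called, 6 adjusted over the list alone, camera adjusted p = 1.17e-06, and adjusted p = 0.0404 with an estimated correlation). Neutrophil and acute inflammation genes were lower (1.15e-11, 12 of 28 adjusted over the list alone, adjusted p = 0.320 with an estimated correlation), as in Cxcl5, a neutrophil attractant, with 5.89 ± 3.66 against 69.3 ± 53.7 CPM. All 19 cholesterol synthesis genes were lower, 9 adjusted over the list alone (4.24e-11, adjusted p = 0.320 with an estimated correlation), Hmgcs1 with 265 ± 70.1 against 393 ± 6.37 CPM. Enteric neuron and glia genes (3.61e-10) and the mitochondrial genome (7.38e-11) were higher, both with adjusted p = 0.320 with an estimated correlation. So were smooth muscle genes (0.0410, adjusted p = 0.894 with an estimated correlation), Myh11 with 203 to 2361 CPM against 515 ± 350, and Smox spermidine replicate 1 also held skeletal muscle genes, with Tnnt3 at 277 CPM. The smooth muscle call ended without Smox untreated replicates 2 (0.148) or 3 (0.399) or Smox spermidine replicate 2 (0.200), and turned without Smox spermidine replicate 3 (0.945). Extracellular matrix and remodelling genes were lower (9.5e-05, adjusted p = 0.622 with an estimated correlation), as were endothelial genes (0.000771, adjusted p = 0.602 with an estimated correlation), genes of regenerative epithelium (0.000219, adjusted p = 0.369 with an estimated correlation), immediate early genes (0.000743, adjusted p = 0.320 with an estimated correlation) and the 5 red cell genes (0.00222, adjusted p = 0.486 with an estimated correlation). For B and plasma cell genes camera gave a lower list (0.000308) while the median log2 change was 0.22 and the mean -0.13 (adjusted p = 0.602 with an estimated correlation). This call ended without Smox spermidine replicate 2 (0.253) and the endothelial one without Smox spermidine replicate 1 (0.0533).

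The genotypes differed in their response to spermidine in 569 genes, 427 with a more positive and 142 with a more negative change in Smox. Smox itself was among them (log2 difference -1.28, SE 0.34, adjusted p = 0.0449), since it was at 26.5 and 47.3 CPM in WT and 30.8 and 22.7 CPM in Smox without and with spermidine. Of enteric neuron and glia genes 6 of 15 had a more positive change, 15 adjusted over the list alone (camera adjusted p = 5.47e-12, adjusted p = 0.458 with an estimated correlation), among them Elavl4 (log2 difference 4.74, adjusted p = 0.0319). Duox1, an epithelial NADPH oxidase (-4.01, adjusted p = 0.0497), and Spink4 (-2.01, adjusted p = 0.0459) had a more negative one. The count was 9 without WT untreated replicate 3, 1 without Smox untreated replicate 2 or Smox spermidine replicate 1, 0 without Smox untreated replicate 3, WT spermidine replicate 1 or 2, or Smox spermidine replicate 3, 311 without WT spermidine replicate 3 and 859 without WT untreated replicate 2. With both atypical libraries left out it was 10, of which 7 were shared, and Smox (0.0526), Elavl4 (0.0689), Duox1 (0.102) and Spink4 (0.0563) were not called.

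Between genotypes with spermidine, 6 genes were higher and 10 lower in Smox. Apart from Eif3j1 (10.3-fold lower, adjusted p = 1.57e-09) and its neighbours, these included Plk3, a stress-responsive kinase, at 21.1 ± 3.96 against 72.8 ± 13.4 CPM (3.44-fold, adjusted p = 0.0139). Trib1, an immediate early pseudokinase, was 2.54-fold lower (adjusted p = 0.0386) and the epithelial kinase gene Ripk4 2.001-fold lower (adjusted p = 0.00616). T and NK cell genes were higher in 18 of 18 members, 13 of them adjusted over the list alone (camera adjusted p = 5.56e-06, adjusted p = 0.629 with an estimated correlation), a call that ended without Smox spermidine replicate 1 (0.524). Immediate early genes (0.000109), clock genes (0.000227) and p53 targets (0.0151) were lower, each with adjusted p = 0.359 with an estimated correlation. The count was 4 without WT spermidine replicate 2 or Smox spermidine replicate 1, 5 without WT spermidine replicate 3, 10 without Smox spermidine replicate 2 and 6 without Smox spermidine replicate 3, and DESeq2 called 225.

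AOM-DSS was compared with untreated colon to see what the carcinogen and repeated injury leave in tissue without tumors. In WT mice Aqp4, a water channel, rose 17.95-fold from 36.6 ± 10.6 to 656 ± 266 CPM (log2 SE 0.71, adjusted p = 0.0110). Khdc1a, an RNA-binding protein gene, rose 167-fold to 36.6 ± 10.8 CPM (adjusted p = 0.01) and Smox 1.77-fold to 46.9 ± 4.61 CPM (adjusted p = 0.0446). Slc51a, a bile acid exporter subunit, fell 428-fold from 67.3 ± 71.1 CPM (adjusted p = 0.0122) and Cyp4b1, a xenobiotic-metabolising P450, 195-fold from 95.7 ± 88.6 CPM (adjusted p = 0.0122). Mylk, the kinase of smooth muscle myosin, fell 5.90-fold (adjusted p = 0.0258).

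Neutrophil and acute inflammation genes rose (6 of 28, 11 adjusted over the list alone, camera adjusted p = 4.24e-07), S100a9 126-fold. Cholesterol synthesis genes rose (5 of 19, 10 adjusted over the list alone, 2.59e-06), Fdps 1.99-fold. Smooth muscle genes fell (3 of 15, also 3 adjusted over the list alone, 1.25e-06), and enteric neuron and glia genes fell (7 of 15, 13 adjusted over the list alone, 1.25e-06). These lists had adjusted p = 0.446 with an estimated correlation. Xenobiotic metabolism genes fell (6 of 27, 8 adjusted over the list alone, 8.28e-05, adjusted p = 0.447 with an estimated correlation), and so did interferon response genes such as Ifit1, 26.0-fold (5 of 25, 8 adjusted over the list alone, 0.00745, adjusted p = 0.727 with an estimated correlation). Adipocyte genes (2 of 10 fell, 8 adjusted over the list alone, 0.00745, adjusted p = 0.468 with an estimated correlation) and small intestine enterocyte genes (3 of 14 fell, 6 adjusted over the list alone, 0.00133, adjusted p = 0.446 with an estimated correlation) were lower. The adipocyte call ended without WT untreated replicate 3 (0.266), and the interferon call without that library (0.176) or WT AOM-DSS replicate 1 (0.252). Of the skeletal muscle genes 8 of 12 fell, Tnnt3, a troponin, from 619 ± 1070 CPM, where WT untreated replicate 3 had 1854. In all, 345 genes rose and 915 fell. The count was 9 without WT untreated replicate 3, 16 without WT AOM-DSS replicate 2, 481 without WT AOM-DSS replicate 3 and 1941 without WT untreated replicate 2. With both atypical libraries left out it was 57, of which 53 were shared, and Aqp4 (0.0433), Khdc1a (0.0161), Slc51a (0.0161) and Cyp4b1 (0.0161) stayed past the threshold while Smox (0.0608), Mylk (0.0861), S100a9 (0.156), Fdps (0.096), Ifit1 (0.276) and Tnnt3 (0.567) did not.

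In Smox mice AOM-DSS raised 1 gene and lowered 14 in non-tumor colon. Pam, which amidates peptide hormones, rose 2.70-fold from 111 ± 24.2 to 299 ± 44.4 CPM (adjusted p = 0.0105). Cps1, the mitochondrial carbamoyl phosphate synthetase, fell 43.6-fold from 28.9 ± 6.09 to 0.66 ± 0.18 CPM (log2 SE 0.83, adjusted p = 0.00693), and Osr2, a transcription factor, 345-fold from 56.5 ± 8.19 CPM (adjusted p = 0.0299). Hoxd10, which patterns the hindgut, fell 19.5-fold (adjusted p = 0.0321), as did 1 of 6 distal hindgut position genes, 4 adjusted over the list alone (camera adjusted p = 0.000138, adjusted p = 0.427 with an estimated correlation). Smox stayed at 29.9 ± 5.25 CPM (adjusted p = 0.967). Xenobiotic metabolism genes were lower (0 of 27 called, 13 adjusted over the list alone, 2.51e-09). So were squamous genes (14 of 14 adjusted over the list alone, 2.34e-07), high in Smox untreated replicate 3. Estimated correlations gave adjusted p = 0.427 and 0.472. The count was 4, 25 and 5 without Smox untreated replicates 1, 2 and 3, and 1, 0 and 3 without those of Smox AOM-DSS. It was 164 without both atypical libraries, 61 in a model of only the groups compared, 761 with the position genes as a covariate, 9 without a filter and 526 by DESeq2.

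No gene differed between genotypes in its response to AOM-DSS in edgeR, with 3088 at an unadjusted p under 0.05, and DESeq2 called 1243. The count was 203 without WT untreated replicate 1, 415 without WT untreated replicate 2 and 460 without Smox AOM-DSS replicate 3. Enteric neuron and glia genes (14 of 15 adjusted over the list alone, camera adjusted p = 1.20e-13) and the mitochondrial genome (15 of 15, 1.05e-13) had a more positive change in Smox, both with adjusted p = 0.489 with an estimated correlation. Without both atypical libraries their median log2 differences of 3.97 and 2.20 shrank to 3.00 and 1.21. Across 19558 genes, which are not independent replicates, the AOM-DSS effects in WT and Smox correlated with r = 0.312 and rho = 0.0769. Those of spermidine alone correlated with r = -0.315 and rho = -0.391. The first r was 0.176 without WT untreated replicate 3, and the second was -0.0516 without Smox spermidine replicate 1, -0.156 and -0.175 without WT spermidine replicates 1 and 2, -0.162 without Smox spermidine replicate 3 and -0.189 without Smox untreated replicate 2.

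Between genotypes after AOM-DSS alone, 7 genes were higher and 6 lower in Smox. Beside the genes near Smox, Bend7, a BEN domain gene of chromosome 2 (4717831 to 4802142), was 9.90-fold higher, at 4.69 ± 3.43 against 0.47 ± 0.05 CPM (adjusted p = 0.00384), and Rab11fip4, of endosome recycling, 2.69-fold lower (adjusted p = 0.0445). Neutrophil and acute inflammation genes were higher in 28 of 28 members with 2 past the threshold adjusted over the list alone (camera adjusted p = 2.44e-08), and tuft cell genes in 10 of 11 (0.0344), both with adjusted p = 0.903 with an estimated correlation. The distal hindgut position genes were lower (0 of 6 called, 4 adjusted over the list alone, 0.0218, adjusted p = 0.903 with an estimated correlation), Hoxd13 with 3.59 ± 1.61 against 69.2 ± 87.4 CPM. The tuft cell call ended without replicate 2 of WT (0.260) or Smox (0.159), and that of the position genes without WT replicate 1 (0.633) or Smox replicates 1 (0.0749) and 3 (0.0703). The count was 5 without WT AOM-DSS replicate 3, 25 without both atypical libraries and 1 in a model of only the groups compared, and DESeq2 called 125.

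Spermidine given during AOM-DSS called no gene in non-tumor colon of WT mice in edgeR, with 1109 at an unadjusted p under 0.05, and DESeq2 called 46. Interferon response genes were higher with spermidine in 25 of 25 members, from a mean log2 CPM of 2.37 ± 0.81 to 4.19 ± 0.57 (camera adjusted p = 7.97e-14, adjusted p = 0.598 with an estimated correlation). Cell cycle genes were higher in 26 of 26 (median log2 change 0.48, 4.21e-08, adjusted p = 0.669 with an estimated correlation), with Mki67 at 275 ± 82.3 against 191 ± 111 CPM, but were not called without WT AOM-DSS replicate 3 (0.160). The distal hindgut position genes moved the same way (1 of 6 adjusted over the list alone, 3.01e-05, adjusted p = 0.598 with an estimated correlation). Enteric neuron and glia genes were lower (3.52e-09, adjusted p = 0.598 with an estimated correlation), and so were B and plasma cell genes (1.98e-06, adjusted p = 0.669 with an estimated correlation). Smox was at 49.4 ± 4.05 and 46.9 ± 4.61 CPM with and without spermidine. Without WT AOM-DSS replicate 1 the count was 1.

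In Smox mice spermidine during AOM-DSS also called no gene in edgeR (2676 at an unadjusted p under 0.05, 409 by DESeq2). B and plasma cell genes were lower in all 16 members, 15 adjusted over the list alone (camera adjusted p = 1.96e-12, adjusted p = 0.410 with an estimated correlation), Igha with 144 ± 105 against 2118 ± 865 CPM. Epithelial antimicrobial genes were lower (0 of 17 called, 1 adjusted over the list alone, 4.53e-06, adjusted p = 0.0528 with an estimated correlation), Saa1 with 415 ± 233 against 1038 ± 760 CPM. Wnt target genes (9 of 23 adjusted over the list alone, 0.000904, adjusted p = 0.781 with an estimated correlation) and Paneth cell genes (5 of 7, 0.0406, adjusted p = 0.736 with an estimated correlation) were higher, and turned lower with both atypical libraries left out (0.895 for both) or only Smox AOM-DSS spermidine non-tumor replicate 1 (0.914 and 0.915). The Paneth cell call also ended without Smox AOM-DSS replicate 2 (0.141) or 3 (0.0961). Without Smox AOM-DSS replicate 3 the count was 2, and it was 10, 2 and 5 without replicates 1, 2 and 3 of the group with spermidine and 21 without both atypical libraries.

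No gene differed between genotypes in the effect of spermidine during AOM-DSS in edgeR (820 at an unadjusted p under 0.05, 68 by DESeq2). Interferon response genes had a more negative change in Smox (camera adjusted p = 3.80e-10, adjusted p = 0.430 with an estimated correlation), as did cholesterol synthesis genes (1.26e-09, adjusted p = 0.430 with an estimated correlation). Without Smox AOM-DSS spermidine non-tumor replicate 3 the count was 1. The study pairs the deletion with the supplement, so the effect of Smox after AOM-DSS was set against that of spermidine in Smox mice after AOM-DSS. Across 19558 genes they correlated with r = -0.602, where sharing the Smox AOM-DSS libraries alone gave a mean of -0.503 in 50 simulations of unchanged groups (-0.525 to -0.482). This rests on single libraries: without Smox AOM-DSS spermidine replicate 2 r was -0.417 where simulations gave -0.470 to -0.426, and without Smox AOM-DSS replicate 2 it was -0.612 where they gave -0.624 to -0.578.

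Between genotypes in non-tumor colon after AOM-DSS with spermidine, 33 genes were higher and 16 lower in Smox. Abca12, a lipid transporter of keratinocytes, was 370-fold higher (log2 8.53, adjusted p = 0.0351), but not called without replicate 3 of the Smox group (log2 3.27) or any one of WT. Fabp6, a bile acid-binding protein, was 13.6-fold lower, at 1.43 ± 0.74 against 19.5 ± 3.78 CPM (log2 SE 0.71, adjusted p = 0.0233). B4galt1, a galactosyltransferase, was 2.08-fold lower (140 ± 35.6 against 292 ± 4.68 CPM, adjusted p = 0.0271). Hoxd10 was 13.4-fold lower (adjusted p = 0.0444), and 1 of 6 distal hindgut position genes fell, 4 adjusted over the list alone (camera adjusted p = 2.71e-07, adjusted p = 0.199 with an estimated correlation). Tuft cell genes were higher in 11 of 11, 6 adjusted over the list alone (8.27e-08, adjusted p = 0.199 with an estimated correlation), and cholesterol synthesis genes lower in 19 of 19, 11 adjusted over the list alone (6.88e-14, adjusted p = 0.257 with an estimated correlation). The higher alpha-defensins (0.000236) and Wnt target genes (0.00566), both with adjusted p = 0.813 with an estimated correlation, turned lower with both atypical libraries left out (0.473 and 0.670) or only replicate 1 of the Smox group (0.492 and 0.754). The count was 4, 5 and 10 without replicates 1, 2 and 3 of the WT group, 444 and 8 without replicates 2 and 3 of the Smox group and 154 without both atypical libraries, where Hoxd10 (0.0511) was no longer called.

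Tumors were compared with non-tumor colon to describe the tumors themselves. In Smox mice after AOM-DSS, 2235 genes rose and 2585 fell in tumors. The stem cell receptor Lgr5 rose 72.2-fold to 91.1 ± 61.8 CPM (log2 SE 1.36, adjusted p = 0.00619), the Wnt inhibitor Notum (chromosome 11, 120653788 to 120661175) 154-fold to 239 ± 239 CPM (adjusted p = 0.0115) and Wif1, another, 124-fold (adjusted p = 0.00733). Lysozyme of Paneth cells, Lyz1, rose 240-fold from 5.35 ± 4.36 to 1288 ± 914 CPM (adjusted p = 0.0107). The chloride exchanger Slc26a3 of mature colonocytes fell 37.9-fold from 371 ± 44.4 to 9.77 ± 7.66 CPM (adjusted p = 0.00487) and the goblet cell lectin Zg16 25.9-fold from 2282 ± 501 to 88.1 ± 37.4 CPM (adjusted p = 0.00173). Smox rose 1.90-fold to 56.8 ± 12.4 CPM (adjusted p = 0.0115).

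Of Wnt target genes 20 of 23 rose in Smox tumors, also 20 adjusted over the list alone (camera adjusted p = 1.26e-10), and of alpha-defensins, antimicrobial peptides of Paneth cells, 17 of 22, 21 adjusted over the list alone (4.26e-13). Paneth cell genes rose in 5 of 7 (6 adjusted over the list alone, 0.000104), colonocyte genes fell in 14 of 25 (18 adjusted over the list alone, 1.85e-09), xenobiotic metabolism genes fell in 20 of 27 (21 adjusted over the list alone, 2.16e-08) and enteric neuron and glia genes in 13 of 15 (also 13 adjusted over the list alone, 1.85e-09). Each of these had adjusted p = 0.362 with an estimated correlation. Cell cycle genes rose in 6 of 26, 8 adjusted over the list alone, Mcm2, a replication helicase subunit, 3.05-fold (5.34e-06). Squamous genes rose in 5 of 14, 6 adjusted over the list alone (0.00766). Both had adjusted p = 0.516 with an estimated correlation. B and plasma cell genes fell in 7 of 16, 11 adjusted over the list alone (2.43e-06). The distal hindgut position genes rose in 4 of 6 (0.00253), Hoxd13 48.3-fold to 174 ± 31.0 CPM. An estimated correlation gave both lists 0.400. This non-tumor group was low in position genes, which did not rise in WT tumors. The 5 pancreas genes (3 rose, 0.0815), the polyamine metabolism list (4 of 27 rose and 2 fell, 0.505) and the endothelium list (0.859) were not called. The count was 990 and 1038 without Smox tumor replicates 1 and 2, 2376 and 2493 without Smox AOM-DSS replicates 2 and 3, and 3087 in a model of only the groups compared.

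Tumors of WT mice after AOM-DSS with spermidine gave 3304 genes that rose and 3418 that fell against non-tumor colon of the same treatment. Notum rose 2273-fold from 0.17 ± 0.08 to 394 ± 239 CPM (log2 SE 2.28, adjusted p = 0.00121), Wif1 645-fold (adjusted p = 0.00078) and Lyz1 147-fold (adjusted p = 0.0077). Lcn2, an iron-binding antibacterial protein, rose 196-fold to 108 ± 40.1 CPM (adjusted p = 0.00127) and Il23a, a cytokine subunit, 69.4-fold (adjusted p = 0.000696). Arg1, arginase, rose 75.1-fold to 38.9 ± 27.3 CPM (adjusted p = 0.0105) and Smox 2.83-fold from 49.4 ± 4.05 to 140 ± 25.3 CPM (log2 SE 0.24, adjusted p = 0.000335). Des, the intermediate filament of muscle, fell 75.3-fold from 193 ± 15.9 to 2.56 ± 1.99 CPM (adjusted p = 0.00204), and Slc26a3 36.4-fold (adjusted p = 0.00126).

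Wnt target genes (20 of 23 rose, 20 rose and 1 fell adjusted over the list alone, camera adjusted p = 4.31e-09), alpha-defensins (19 of 22, all 22 adjusted over the list alone, 7.38e-14) and regenerative epithelium genes such as Cldn4 (11 of 15, 7.06e-05) were higher in WT tumors, each with adjusted p = 0.350 with an estimated correlation. Neutrophil and acute inflammation genes rose in 18 of 28, 24 adjusted over the list alone (3.15e-07, adjusted p = 0.449 with an estimated correlation). Smooth muscle genes fell in 13 of 15, 14 adjusted over the list alone (1.04e-07), and goblet cell genes in 11 of 16, 13 adjusted over the list alone (3.62e-06), both with adjusted p = 0.403 with an estimated correlation. Enteroendocrine genes such as Gcg, the glucagon precursor, fell in 13 of 16 (3.48e-08, adjusted p = 0.350 with an estimated correlation). Interferon response genes fell in 9 of 25, 12 adjusted over the list alone (8.99e-05, adjusted p = 0.582 with an estimated correlation), and cholesterol synthesis genes in 8 of 19, 9 adjusted over the list alone (0.00263, adjusted p = 0.583 with an estimated correlation). The polyamine metabolism list was not called (9 of 27 rose and 4 fell, 0.214), nor were cell cycle genes (0 of 26, 0.396), NRF2 and redox enzymes (2 of 17 rose and 4 fell, 0.444), p53 targets (4 of 15 rose and 3 fell, 0.609) or the position genes (0 of 6, 0.952). The count was 4404 without WT tumor replicate 1.

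The 2 tumor effects were alike across genes, with r = 0.684 and rho = 0.662 over 19558 genes that are not independent replicates. In both, 1436 genes rose where independence of the called genes gives 378, and 1618 fell where it gives 452, while 7 were called in opposite directions. A test of the difference called 2 genes, with more positive log2 changes in Smox tumors for Cps1 (7.16, SE 1.07, adjusted p = 0.0155) and Insm1, a transcription factor of enteroendocrine cells (4.22, SE 0.67, adjusted p = 0.0192). Cps1 was at 0.66, 15.5, 29.1 and 4.76 CPM, and Insm1 at 2.49, 2.97, 14.8 and 0.94, in Smox non-tumor and tumor and WT non-tumor and tumor tissue. For enteric neuron and glia genes camera gave a lower list (0.0272, adjusted p = 0.791 with an estimated correlation) while the median and mean log2 difference were 0.44 and 0.66, a call that ended without Smox AOM-DSS non-tumor replicate 2 (0.201), WT AOM-DSS spermidine non-tumor replicate 1 (0.182) or Smox tumor replicates 1 (0.395) and 2 (0.119). The count was 0 without any 1 of the 3 Smox AOM-DSS non-tumor libraries or of WT tumor replicates 1 and 3, 1 without WT AOM-DSS spermidine non-tumor replicate 1 or Smox tumor replicate 3, 4 without Smox tumor replicate 2 and 36 without WT tumor replicate 2. It was 132 in a model of only the groups compared and 260 by DESeq2.

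Smox tumors after AOM-DSS were also set against WT tumors after AOM-DSS with spermidine, a comparison in which genotype and supplement differ together. Here 7 genes were higher and 5 lower in Smox tumors. Clip4, a linker of microtubules, was 15.9-fold higher, at 3.03 ± 1.43 against 0.19 CPM (adjusted p = 0.0251), and Smox 2.46-fold lower (adjusted p = 0.0357). Smooth muscle genes were higher in 14 of 15, 9 adjusted over the list alone (camera adjusted p = 6.84e-07), enteric neuron and glia genes in 13 of 15, 11 adjusted over the list alone (5.73e-07), and enteroendocrine genes in 14 of 16, 5 adjusted over the list alone (5.97e-07), each with adjusted p = 0.909 with an estimated correlation. The smooth muscle call ended without Smox tumor replicate 3 (0.136). The count was 6 without WT tumor replicate 1 and 3 in a model of only the groups compared, and DESeq2 called 147.

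**Figure D4:**
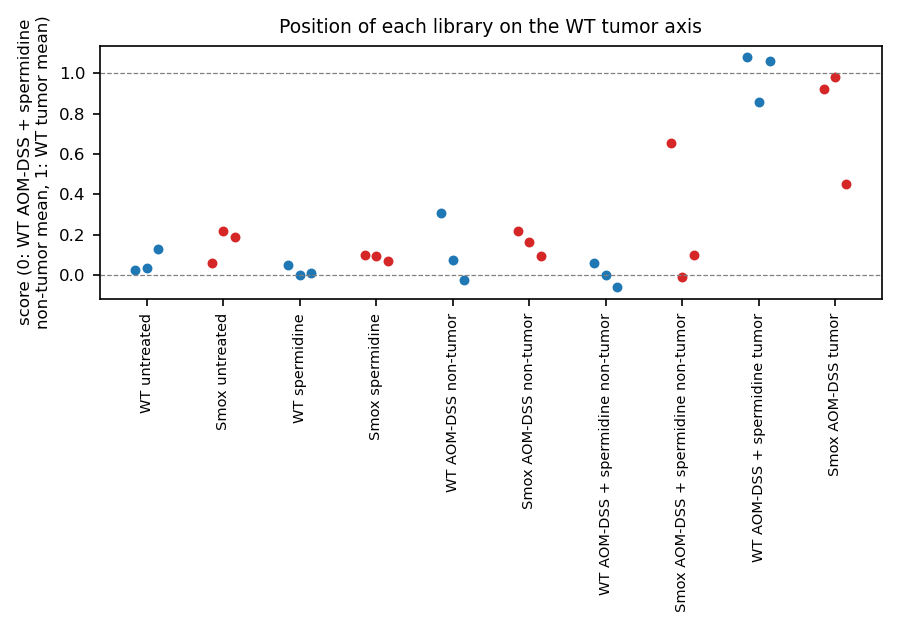
Position of each library between the mean of WT AOM-DSS spermidine non-tumor colon, set to 0, and the mean of WT tumors, set to 1 (blue WT, red Smox). The 6722 genes called in that comparison place Smox AOM-DSS spermidine non-tumor replicate 1 at 0.653 and Smox tumor replicate 3 at 0.452, while the other non-tumor libraries lie at 0.305 or below and the other tumors at 0.857 or above.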

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

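The tests of donor-strain DNA, of Eif3j1 reads, of tissue of another kind, of depth, of tumor tissue and of a label swap were chosen only after the results were seen, and so was the look at which libraries a split brings together, while the alignments of Pcna-ps2 and Gm18234 and the counts of splits were chosen before. The differences given first were called by a test of the difference between 2 effects, and the 3 patterns weighed after them were found in the data. A library far from the rest of its group was not searched for by a test, since groups of 3 are too small for it.

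The spermidine effect differed between the genotypes in 569 genes by edgeR. It was more positive in Smox for Phkg1, the catalytic subunit of muscle phosphorylase kinase (log2 difference 7.90, adjusted p = 0.0382), for the potassium channel gene Kcnc2 (5.39, SE 1.32, 0.0340), for Ndst4, an enzyme of heparan sulfate synthesis (5.20, SE 1.24, 0.0323), for the glutamate receptor gene Gria2 (5.14, SE 1.16, 0.0314) and for Eef1a2, a translation elongation factor of muscle and neurons (5.14, SE 1.32, 0.0418). It was more negative for Sprr2b, a cornified envelope protein (-5.69, SE 1.49, 0.0432), Duox1 (-4.01, SE 1.11, 0.0497), the epithelial transcription factor gene Grhl3 (-3.45, SE 0.95, 0.0497), Spink4 (-2.01, SE 0.54, 0.0459) and the TNF receptor gene Tnfrsf1b (-1.95, SE 0.49, 0.0367). None of these 10 stayed past the threshold without WT untreated replicate 3, Smox untreated replicate 2 or 3, WT spermidine replicate 1 or 2, or Smox spermidine replicate 1 or 3, and the count was then 9, 1, 0, 0, 0, 1 and 0 in that order, against 311 without WT spermidine replicate 3 and 859 without WT untreated replicate 2. Of 100 splits of these 12 libraries 2 gave as many genes, a share under 0.05. The highest other split gave 1056 by exchanging WT spermidine replicate 3 with Smox spermidine replicate 2, which points to a structure of the samples besides the named groups.

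Lists with a more negative spermidine effect in Smox (median log2 difference, camera adjusted p) were neutrophil and acute inflammation (-3.36, 5.24e-06), interferon response (-0.84, 0.00535), epithelial antimicrobial response (-2.34, 0.000273), NRF2 and redox enzymes (-0.52, 0.00130), cholesterol synthesis (-0.48, 0.000277), colonocyte (-0.74, 0.0128) and goblet cell (-0.92, 0.00130). Smooth muscle (2.09, 0.00472), enteric neuron and glia (3.95, 5.47e-12) and mitochondrial genome (1.94, 9.15e-10) had a more positive one. With an estimated correlation no list was called, the adjusted p being 0.239 to 0.891. The interferon call ended without WT untreated replicate 1 (0.104) or 2 (0.0777), Smox untreated replicate 2 (0.0892) or Smox spermidine replicate 3 (0.272), and smooth muscle without the last (0.0903). The colonocyte call ended without WT untreated replicate 2 (0.0846), Smox untreated replicate 1 (0.0627), WT spermidine replicate 3 (0.0878) or Smox spermidine replicate 2 (0.0526).

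For AOM-DSS, edgeR called 0 genes whose effect differed between the genotypes, with 3088 at an unadjusted p under 0.05 and 1243 called by DESeq2. The lists with a more negative effect in Smox were neutrophil and acute inflammation (-2.10, 0.00713), epithelial antimicrobial response (-1.04, 0.0191), cell cycle (-0.64, 0.00713), cholesterol synthesis (-0.31, 0.0204), goblet cell (-1.18, 0.00444), B and plasma cell (-2.32, 0.00713), T and NK cell (-0.88, 0.00713), macrophage (-0.80, 0.0436), distal hindgut position genes (-3.11, 0.0226), Paneth cell (higher in 0 of 7 members, 0.0299) and squamous epithelium (0 of 14, 0.00713). Smooth muscle (2.32, 3.09e-05), enteric neuron and glia (3.97, 1.20e-13) and mitochondrial genome (2.20, 1.05e-13) had a more positive one. With an estimated correlation the adjusted p was 0.489 to 0.873. Smooth muscle, enteric neuron and glia and mitochondrial genome stayed called with each library left out in turn, and the other calls ended at least once. Without WT untreated replicate 1 this held for neutrophil (0.0693), antimicrobial (0.0782), cholesterol (0.107), Paneth (0.0844), B and plasma (0.112), T and NK (0.0782) and macrophage genes (0.56), without replicate 2 for Paneth (0.109), T and NK (0.109) and squamous genes (0.0684), and without replicate 3 for cell cycle (0.89) and position genes (0.734). Without Smox untreated replicate 2 it held for neutrophil (0.309), cell cycle (0.114), Paneth (0.0781) and macrophage genes (0.252), without replicate 1 for position genes (0.0809) and without replicate 3 for squamous genes (0.55). Without WT AOM-DSS replicate 1 it held for neutrophil (0.169), cell cycle (0.743), Paneth (0.293), macrophage (0.293) and position genes (0.293), without replicate 2 for cholesterol (0.349), and without replicate 3 for cholesterol (0.252), goblet (0.0853) and B and plasma cell genes (0.0589). Without Smox AOM-DSS replicate 1 it held for antimicrobial (0.0598), cholesterol (0.069), macrophage (0.141) and position genes (0.0666), without replicate 2 for neutrophil genes (0.171), and without replicate 3 for Paneth (0.0666), macrophage (0.0552) and position genes (0.0552). With a real count of 0 each of the 100 splits gives as many, which says nothing on chance, and the highest gave 336 by exchanging the third AOM-DSS libraries of WT and Smox, which points to a structure of the samples.

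For spermidine during AOM-DSS, edgeR called 0 genes as well, with 820 at an unadjusted p under 0.05 and 68 called by DESeq2. The lists with a more negative effect in Smox were interferon response (-1.83, 3.80e-10), epithelial antimicrobial response (-0.61, 0.00303), cholesterol synthesis (-0.56, 1.26e-09), B and plasma cell (-2.26, 0.000417) and distal hindgut position genes (-0.70, 0.000711). Those with a more positive one were Wnt target genes (2.01, 0.000234), tuft cell (1.16, 0.000303), Paneth cell (higher in 7 of 7 members, 5.26e-05) and alpha-defensins (21 of 22, 2.59e-05). With an estimated correlation the adjusted p was 0.425 to 0.683. Without Smox AOM-DSS spermidine replicate 1 the Wnt call ended (0.841) and the alpha-defensins turned (0.796), and without both atypical libraries the Paneth cell call ended (0.0706). Without WT AOM-DSS replicate 1 the calls of Wnt (0.501), alpha-defensin (0.0519) and B and plasma cell genes (0.0786) ended, and the last also without WT AOM-DSS spermidine replicate 2 (0.303). With a real count of 0 each of the 100 splits again gives as many. The highest gave 1813 and points to a structure of the samples: it brings together WT AOM-DSS replicate 1 and Smox AOM-DSS replicates 1 and 2, with scores on the axis from WT non-tumor to WT tumor tissue of 0.305, 0.220 and 0.161, against 0.0921 or less in the other 3.

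The tumor effects of Smox and of WT with spermidine, unadjusted for position genes, differed in 2 genes, Cps1 (log2 difference 7.16, adjusted p = 0.0155) and Insm1 (4.22, 0.0192). The count was 0 without any 1 of the 3 Smox AOM-DSS non-tumor libraries or WT tumor replicate 1 or 3. It reached 36 without WT tumor replicate 2. Lists with a more negative effect in Smox were neutrophil and acute inflammation (-3.37, 8.24e-07), extracellular matrix and remodelling (-1.22, 0.00297), macrophage (-1.07, 0.00170), endothelium (-1.53, 0.0146), mitochondrial genome (-0.78, 0.00128), alpha-defensins (higher in 3 of 22 members, 0.0272) and, by camera, enteric neuron and glia (0.44, 0.0272). Those with a more positive one were interferon response (2.24, 1.15e-07), cell cycle (0.81, 0.000118), cholesterol synthesis (0.48, 0.000241), enteroendocrine cell (1.71, 0.000169), smooth muscle (1.91, 0.0322) and distal hindgut position genes (4.50, 0.000241). With an estimated correlation the adjusted p was 0.791 for each. Without Smox AOM-DSS non-tumor replicate 1 the calls of extracellular matrix (0.0512), alpha-defensin (0.0757), smooth muscle (0.148) and endothelium genes (0.0908) ended, without replicate 2 those of alpha-defensin (0.122), enteric neuron (0.201) and endothelium genes (0.0999), and without replicate 3 that of smooth muscle (0.228). Without WT AOM-DSS spermidine non-tumor replicate 1 those of smooth muscle (0.0589) and enteric neuron genes (0.182) ended, without replicate 2 those of alpha-defensin (0.0966), smooth muscle (0.0545) and endothelium genes (0.0778), and without replicate 3 that of the extracellular matrix (0.0752). Without WT tumor replicate 1 it was alpha-defensins (0.313) and smooth muscle (0.149). Without Smox tumor replicate 1 it was alpha-defensins (0.0515) and enteric neuron genes (0.395), without replicate 2 the latter (0.119), and without replicate 3 alpha-defensins (0.995) and smooth muscle (0.932). Of 100 splits 4 gave as many genes, a share under 0.05. The highest other split gave 101 by exchanging WT tumor replicates 2 and 3 with Smox tumor replicates 2 and 3, and points to a structure of the samples.

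Genes of chromosome 2 and near-identical copies of such genes differed between Smox and WT libraries in untreated colon, with spermidine, after AOM-DSS, after AOM-DSS with spermidine and in tumors. For reads of a gene near Smox in Gm18234, the prediction was not fully met. Its closest other annotated gene, Zfp106, lies within 20 Mb of Smox, as predicted, but at 88.1% identity, under the 90% set beforehand. By that rule the identity argues against such reads in Gm18234, though the place of Zfp106 goes with them. DNA of a donor strain flanking the Smox deletion may contribute, since with the 8 recurring genes left out 28 of 338 genes within 20 Mb of Smox differed one way in all 5 comparisons, at an unadjusted p under 0.05 in at least 3, against 0.77% of genes elsewhere (Fisher's exact p = 3.77e-19). Reads of Eif3j1 assigned to Eif3j2 and of Pcna assigned to Pcna-ps2 stay open, since the summed CPM of the first 2 differed by -0.322 WT SDs while Eif3j1 differed by -5.97 and Eif3j2 by 4.35, and Pcna-ps2 was 99.2% identical to Pcna. An effect of the lost enzyme on these genes, the difference the design names, stays open as untested.

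More than 1000 genes were called in both comparisons with the untreated WT libraries, Smox against WT and AOM-DSS in WT. Thinning argues against depth as the origin: with each library drawn down at random to the total of the smallest, 1073 and 1099 genes were called, at least 0.872 of the counts, and 959 and 1016 of them were shared. Tissue of another kind in WT untreated replicate 3 is a candidate explanation: 12 of 12 skeletal muscle genes, a list drawn up after that library was seen and so only a description of it, were highest there, with Tnnt3 at 1854 CPM against 277 in the next. Leaving that library out lowered most, in 2 of 2 comparisons, the median absolute log2 fold change of the called genes, to 1.52 from 2.21 and to 1.47 from 2.25, and 17 and 9 genes were called, though 6 were called without Smox untreated replicate 2 or 3, 16 without WT AOM-DSS replicate 2 and 481 without WT AOM-DSS replicate 3. The genotype and AOM-DSS, which the design names, stay open as untested.

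Smox AOM-DSS spermidine non-tumor replicate 1 carried tumor genes. A label swap with Smox tumor replicate 3 stays open. That tumor scored 0.452, above all other non-tumor libraries (0.305 or less) but below this library. Tumor tissue in the sample is a candidate only, as its test restates the pattern. The sample scored 0.653, below the other tumors (0.857 or more). Its alpha-defensin, Wnt target and Paneth cell genes exceeded all other non-tumor libraries. Another exchanged label was not tested. Spermidine given to Smox mice during AOM-DSS, the difference the design names, stays open as untested, with replicates 2 and 3 of that group at -0.00864 and 0.101.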

How the results depend on the processing

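The model without both atypical libraries, the model with the position genes as a covariate, the window of 20 Mb and each setting for genes called in all 5 comparisons of Smox with WT were chosen only after the results were seen. Of 421 named genes that passed the test, 278 stayed past it without both atypical libraries, 408 with DESeq2 and 410 with RLE scaling. It was 281 without a filter, 401 with a filter of 1 CPM in 3 libraries and 204 in models of only the groups compared. None turned in these settings. Without both atypical libraries 197 of 232 called lists stayed called on the same side, 5 turned and 30 ended. Another 4 lists were called only then, on the other side. Many of these genes and lists belong to comparisons holding neither library. The 4 genotype genes Eif3j1, Jmjd7, Pcna-ps2 and Spg11 were called in all 5 comparisons with RLE scaling, DESeq2, either other filter and without both atypical libraries. In simulated data 46 to 58% of 2-fold and 83 to 89% of 4-fold changes were recovered. The smallest library, WT AOM-DSS spermidine non-tumor replicate 3, had 33060607 counts, and leaving it out gave 10 genes between genotypes after AOM-DSS with spermidine. For each value that follows, the cause was not tested unless fewer libraries or fewer genes were used.

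With DESeq2 the number of genes called was 2705 for Smox against WT in untreated colon, 910 and 46 for spermidine in WT and Smox, 225 for Smox against WT with spermidine, 2760 and 526 for AOM-DSS in WT and Smox, 125 for Smox against WT after AOM-DSS, 46 and 409 for spermidine during AOM-DSS in WT and Smox, 752 for Smox against WT after AOM-DSS with spermidine and 147 between the tumors. It was 1783, 1243 and 68 for the genotype difference in the effects of spermidine, of AOM-DSS and of spermidine during AOM-DSS, and 260 for the difference of the tumor effects. DESeq2 called 9 genes in all 5 comparisons of Smox with WT, 4 of which were among the 5 of edgeR.

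Without a filter the count was 592 for Smox against WT in untreated colon, 578 and 9 for AOM-DSS in WT and Smox, 19 for Smox against WT after AOM-DSS with spermidine and 261 for the genotype difference of the spermidine effect. With a filter of 1 CPM in 3 libraries it was 1 for spermidine during AOM-DSS in Smox and 75 for the genotype difference of the AOM-DSS effect, which gave 1 gene with RLE scaling.

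In models of only the groups compared, which hold fewer libraries, the count was 1 for Smox against WT in untreated colon, 0 for spermidine in WT, 6 for Smox against WT with spermidine, 0 and 61 for AOM-DSS in WT and Smox, 1 for Smox against WT after AOM-DSS, 1 after AOM-DSS with spermidine, 3087 for Smox tumors against non-tumor colon, 3 between the tumors and 132 for the difference of the tumor effects.

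Without both atypical libraries the count was 32 for Smox against WT in untreated colon, 52 for spermidine in WT, 57 and 164 for AOM-DSS in WT and Smox, 25 for Smox against WT after AOM-DSS, 21 for spermidine during AOM-DSS in Smox, 154 for Smox against WT after AOM-DSS with spermidine, 10 and 1 for the genotype difference of the spermidine and the AOM-DSS effect and 21 for the difference of the tumor effects. The correlation of the AOM-DSS effects of the genotypes was 0.176. Lists that turned their direction were the cell cycle with spermidine in WT (adjusted p = 0.00795) and with AOM-DSS in WT (0.0162), Wnt target genes (0.895), Paneth cell genes (0.895) and alpha-defensins (0.000492) with spermidine during AOM-DSS in Smox, Wnt target genes (0.67), xenobiotic metabolism (0.00332) and alpha-defensins (0.473) for Smox against WT after AOM-DSS with spermidine, and alpha-defensins (0.69) for the genotype difference of that spermidine effect. With the position genes as a covariate the count was 761 for AOM-DSS in Smox, 25 for spermidine during AOM-DSS in Smox and 2 for the genotype difference of the AOM-DSS effect.

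An estimated correlation left 2 of 232 lists called, and fry called 53, 16 for tumors in Smox, 19 in WT and 0 to 5 per other comparison. Near Smox, called genes were more frequent than elsewhere in untreated colon, with spermidine, after AOM-DSS and after both, within 10 Mb (adjusted p in order 0.00253, 0.000622, 1.35e-05 and 0.00105) and 20 Mb (0.000476, 8.04e-06, 1.73e-07 and 4e-06).

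Leaving out each library of a comparison in turn, the count ran from 6 to 1351 for Smox against WT in untreated colon (lowest without Smox untreated replicate 2), from 0 to 7 for spermidine in WT and from 4 to 15 for Smox against WT with spermidine. It ran from 9 to 1941 for AOM-DSS in WT (lowest without WT untreated replicate 3), from 0 to 25 for AOM-DSS in Smox, from 5 to 14 for Smox against WT after AOM-DSS, from 0 to 1 and from 0 to 10 for spermidine during AOM-DSS in WT and Smox, and from 4 to 444 for Smox against WT after AOM-DSS with spermidine. For tumors it ran from 990 to 6117 in Smox, from 4404 to 6242 in WT and from 6 to 15 between them. For the differences of effects it ran from 0 to 859 (spermidine), 0 to 460 (AOM-DSS), 0 to 1 (spermidine during AOM-DSS) and 0 to 36 (tumors). The correlation across genes of the AOM-DSS effects in WT and Smox ran from 0.176 to 0.433 and that of the spermidine effects from -0.283 to -0.0516.

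Lists that turned in at least 1 of these fits had the following lowest and highest adjusted p. With spermidine they were the cell cycle in WT, 0.00107 to 0.702, and in Smox interferon response, 1.77e-05 to 0.709, smooth muscle, 3.84e-06 to 0.945, T and NK cell, 1.28e-07 to 0.948, and squamous epithelium, 0.000125 to 0.807. For Smox against WT with spermidine it was smooth muscle, 0.0143 to 0.989. With AOM-DSS in WT it was the cell cycle, 0.000156 to 0.202, and for Smox against WT after AOM-DSS the cell cycle, 2.72e-08 to 0.36, and colonocyte, 0.0327 to 0.791. With spermidine during AOM-DSS in WT they were Wnt target genes, 0.0205 to 0.995, cholesterol synthesis, 8.69e-06 to 0.525, goblet cell, 0.02 to 0.97, and endothelium, 0.000499 to 0.837. In Smox they were Wnt target genes, 8.4e-06 to 0.914, xenobiotic metabolism, 4.4e-05 to 0.986, Paneth cell, 0.00558 to 0.915, and alpha-defensins, 0.000224 to 0.757. For Smox against WT after AOM-DSS with spermidine they were Wnt target genes, 7.5e-06 to 0.754, xenobiotic metabolism, 0.00298 to 0.812, and alpha-defensins, 1.89e-08 to 0.492. Between the tumors it was alpha-defensins, 6.15e-05 to 0.57, and for the genotype difference of spermidine during AOM-DSS xenobiotic metabolism, 9.88e-06 to 0.986, and alpha-defensins, 2.12e-08 to 0.796.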

Other observations

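The libraries that a split brings together were looked up only after the counts were seen, while the splits were chosen before.

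Tumors of WT mice given spermidine also differed from non-tumor colon in genes of the matrix, in immediate early genes and in single clock genes. Thbs2, a thrombospondin of the matrix, rose 116-fold to 129 ± 23.7 CPM (adjusted p = 0.00124), and Spp1, osteopontin, 176-fold from 0.20 ± 0.16 CPM (adjusted p = 0.00261, n = 3 each, edgeR). Of 25 extracellular matrix and remodelling genes 8 rose and 2 fell (camera adjusted p = 0.0247, adjusted p = 0.738 with an estimated correlation), a call that ended without WT AOM-DSS spermidine non-tumor replicate 3 (0.219) or WT tumor replicates 2 (0.13) and 3 (0.0974). Jun, a subunit of the transcription factor AP-1, rose 4.70-fold from 80.6 ± 4.83 to 379 ± 27.1 CPM (adjusted p = 0.000353). It was among 5 of 13 immediate early genes that rose (camera adjusted p = 0.0488, adjusted p = 0.573 with an estimated correlation), and that call ended without the same 3 libraries (0.129, 0.0742 and 0.103). The clock list was not called (camera adjusted p = 0.0988), though 5 of its 15 genes fell and 1 rose. The clock output genes Hlf and Dbp fell 8.26-fold (adjusted p = 0.00954) and 3.49-fold (adjusted p = 0.00542), and Nfil3, a repressor that acts on the same promoters, rose 3.87-fold (adjusted p = 0.00389).

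Single marker and carrier genes changed in the same tumors, while the tuft cell and polyamine lists were not called. Avil, a marker of tuft cells, rose 31.9-fold from 3.83 ± 0.35 to 122 ± 39.3 CPM (adjusted p = 0.000365), 1 of 2 tuft cell genes that rose, while 1 of 11 fell (camera adjusted p = 0.557 for the list). Cd68, a macrophage marker, rose 3.48-fold (adjusted p = 0.00619), 1 of 3 macrophage genes that rose while 1 of 15 fell (camera adjusted p = 0.0485, adjusted p = 0.664 with an estimated correlation). That call ended without WT AOM-DSS spermidine non-tumor replicate 3 (0.239) or WT tumor replicates 2 (0.0704) and 3 (0.0546). Of 27 polyamine genes 9 rose and 4 fell (camera adjusted p = 0.214). Slc7a2, a carrier of arginine, rose 18-fold to 8.31 ± 4.07 CPM (adjusted p = 0.000951), and Slc18b1, a carrier of polyamines into vesicles, fell 3.97-fold from 39.4 ± 7.59 to 9.93 ± 4.01 CPM (adjusted p = 0.000197). In tumors of Smox mice Slc18b1 fell 2.84-fold from 34.9 ± 3.56 to 12.3 ± 4.34 CPM (adjusted p = 0.00340).

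For each comparison of 2 groups, 10 splits of the 6 libraries are too few for a share under 0.05. The real split and the highest other gave 1164 and 1 genes for Smox against WT in untreated colon, 1 and 1 for spermidine in WT, 0 and 0 for spermidine in Smox, 16 and 1 for Smox against WT with spermidine and 15 and 0 for AOM-DSS in Smox. They gave 0 and 0 for spermidine during AOM-DSS in WT and in Smox, 49 and 1 for Smox against WT after AOM-DSS with spermidine, 4820 and 1 for tumors in Smox, 6722 and 0 for tumors in WT and 12 and 3 between the tumors. Where edgeR called 0, the genes at an unadjusted p under 0.05 were 1825 for spermidine in Smox and 1109 and 2676 for spermidine during AOM-DSS in WT and Smox, and DESeq2 called 46, 46 and 409.

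For AOM-DSS in WT the real split gave 1260 genes and the highest other 937, by exchanging WT untreated replicate 3 with WT AOM-DSS replicate 1. That exchange brings together the 3 libraries with distal hindgut position genes at a mean of 5.60 to 5.83 log2 CPM, against 0.19 to 3.33 in the other 3. For Smox against WT after AOM-DSS the real split gave 13 and the highest other 329, by exchanging WT replicates 2 and 3 with Smox replicates 1 and 2, so that a structure of the samples other than genotype parts these 6 libraries. The 3 libraries it brings together, WT replicate 1 and Smox replicates 1 and 2, had Wnt target genes at a mean of 3.10 to 4.61 log2 CPM, against 2.20 to 2.26 in the other 3.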
